A study of Homo sapiens with 4 samples.

How the data were processed

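OVCAR5, a human ovarian carcinoma cell line, had been exposed in culture to the supernatant of tumor cells grown with T cells, and all 24 conditions were measured in 1 pool by droplet-based 3′ single-cell RNA sequencing. Per the labels, the conditions were 6 supernatant levels (none, undiluted and dilutions of 5, 25, 125 and 625 times) at 4 exposure times (2, 6, 12 and 24 h). The 4 GEO samples of the series were 2 gene-expression libraries and 2 cell-hashing libraries of that pool, in which oligonucleotide tags on antibodies mark the culture a cell came from.

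The deposited matrix holds counts of unique molecular identifiers (UMIs, each standing for 1 captured RNA molecule) for 36602 genes and 10 hashtags in 10660 cell barcodes. The authors' counts were made with Cell Ranger 5.0.1, per the file headers, while the submitters' processing notes list Cell Ranger 2.1.1 and the build GRCh38. The annotation version and the settings of the cell caller are not given in the sources used here. Gene names and identifiers were taken from the deposited table of features. Coordinates came from GENCODE 29 on GRCh38, matched by gene identifier for 34616 of 36602 genes.

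Barcodes with at least 1000 genes and at most 20% of UMIs in mitochondrial genes were kept. Each barcode was assigned to a pair of tags where both of its highest tag counts were at least 3 times the next one. Pairs that were the top tags of at least 100 barcodes counted as in use, and each of the 24 pairs in use is called a hashtag sample, named by its tags (HTO3/HTO9). The sources used here do not say which tag pair marks which condition. No sample was therefore given a dose or a time, no groups were compared, and the tests planned for known conditions were not run. The hashtag samples are not replicates of one another, and each condition had 1 culture.

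UMI counts of the kept cells were summed per hashtag sample and divided by the sample's total to give CPM, the count in each 1e6 UMIs. Sample totals ran from 1863154 to 3904112 UMIs, so that 3 counts corresponded to between 0.768 and 1.61 CPM. Intervals of 95% are exact Poisson intervals for counts, conditional binomial intervals for ratios of counts and exact binomial intervals for shares, and they cover counting error only. A fold against a sample with 0 counts was computed against 3 counts in that sample and is a lower bound.

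The range of a gene is the difference of log2(CPM + 10) between its highest and lowest sample, for genes with a mean of at least 20 CPM. A level of 16 gene lists was taken as the log2 of the summed CPM of the members + 10. The lists hold 327 genes and were written before the data were examined, as were 48 cell type markers, the filters on cells, the tag margin, the pseudocounts and the settings of clustering. Genes named in the report are the 25 with the widest range and, for each list, the 4 members with the highest mean and the 4 with the widest range, except for a gene that is not reported here. Genes with the largest excess variance, genes that lead clusters, and genes named in the closing section for their values were chosen after these were seen. The ranges of 4-fold for a gene and 2-fold for a list member, the minimum of 100 barcodes, the depth of thinning, the gap rule below, the list pairs that are described, the values without 1 sample and the relations to the mitochondrial share were also chosen after the data were seen.

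Samples were first checked for separate clusters in each list: a gap between neighbouring samples was called wide when it took more than 0.243 of the list's range, the 95th percentile for evenly random values. Only gaps with at least 2 samples on each side were considered, so a sample standing alone was not called separate by this rule. The 6 samples on the smaller side of a wide gap in any list were set apart, and lists were correlated over the other 18. Pearson's r and Spearman's rho were each tested with a two-sided permutation test of 100000 resamples, and p-values were adjusted by the Benjamini-Hochberg method over 120 pairs of lists, or over 16 lists for the mitochondrial share. Intervals of r are Fisher intervals. The tests and intervals treat the samples as independent. The conditions shared doses and exposure times by design, which could not be taken into account. The p-values may therefore be too small and the intervals too narrow.

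For single cells, the variance of each gene's counts was divided by the variance that Poisson sampling gives at each cell's depth, with a ratio of 1.5 or more in genes detected in at least 5% of cells taken as excess. Shares of cells with a UMI and list scores were computed before and after thinning each cell to 3000 UMIs, which left 6314 of 6408 kept cells. Cells were clustered with the Leiden method at resolution 0.5. Scrublet called 2 of 6408 cells doublets (0.0312%), which was taken as a failure of the caller, so that doublets were not removed. Cells without a clear tag pair entered the analyses of the pool and not those of hashtag samples. Their median depth among kept cells was 17091 UMIs, against 13208.5 in assigned cells, and doublets among them were not excluded.

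The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and scikit-learn 1.9.0, and R 4.3.3 with edgeR 4.0.16 for TMM factors in an alternative scaling. The procedures were tested on simulated data. Of 50 genes simulated with an 8-fold range among 5751 genes, 49 were called at the 4-fold threshold, as were 3 of 50 with a true range of 4-fold, 0 of 50 with a true range of 2-fold and 0 of 5551 unchanged genes. For excess variance among 2000 simulated genes, 64 of 65 expected at 1.5 or more were called and 0 of 1800 Poisson genes. Of 120 pairs of unrelated simulated lists, 0 passed the adjusted threshold. Alternatives covered the scaling, pseudocounts, filters on genes and cells, the tag margin, thinning, list members, cluster settings and cells left out.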

Results

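The pool held 10660 barcodes with 105361602 gene UMIs and 18417375 hashtag UMIs. The filters kept 6408 cells (60.1%), with a median of 13526 UMIs, 3769.5 genes and 10.4% mitochondrial UMIs. Of the possible 45 pairs of 10 tags, 24 were in use, each as the top tags of at least 339 barcodes, and no other pair had more than 17. A hashtag sample was found for 5298 kept cells (82.7%), and 1110 stayed without one. Hashtag samples had between 137 cells (HTO7/HTO8) and 272 cells (HTO5/HTO10), with a median of 231.5. The lowest median depth, 9389 UMIs per cell, and the highest median mitochondrial share, 13.8%, were both in HTO3/HTO9.

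The series asks how tumor cells respond to different amounts and durations of exposure to cytokines released by T cells. As no source used here ties a tag pair to a dose or a time, the values below describe how far genes ranged over the 24 hashtag samples and which gene groups moved together.

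Genes induced by interferon gamma, the main antiviral and immune-activating cytokine of T cells, had among the widest ranges. Their summed level ran from 528 CPM in HTO4/HTO8 to 18568 CPM in HTO3/HTO9, a ratio of 35.2 (95% interval 33.3 to 37.2), with a median of 3848 CPM. All 22 members with enough reads ranged by 4-fold or more. CXCL10 (ENSG00000169245, chromosome 4, 76021117 to 76023497), which encodes a chemokine that attracts T cells, ran from 15.5 CPM in HTO4/HTO8 to 3896 CPM in HTO3/HTO9, a ratio of 251 (182 to 356). IDO1 (ENSG00000131203, chromosome 8, 39902275 to 39928444), a tryptophan-degrading enzyme, ran from 10.1 to 2818 CPM between the same samples, a ratio of 280 (188 to 437). The chemokine gene CXCL9 ran from 2.75 CPM in HTO7/HTO9 to 1250 CPM in HTO3/HTO9, and to 525 CPM without HTO3/HTO9. GBP5, a guanylate-binding protein gene, had 0 counts in HTO4/HTO8 and 508 CPM in HTO3/HTO9, at least 403-fold higher, but its next-highest sample had 188 CPM, at least 149-fold without HTO3/HTO9. The transcription factor gene IRF1 was lowest in HTO7/HTO10 (60.1 CPM) and highest in HTO2/HTO10 (1715 CPM), a different sample from most other members named here. Its highest level without HTO2/HTO10 was close, at 1682 CPM. WARS, a tryptophanyl-tRNA synthetase gene, ran from 49.98 to 2514 CPM.

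Genes of antigen presentation also had wide ranges. The MHC class II list ran from 17.5 CPM in HTO2/HTO9 to 2385 CPM in HTO3/HTO9, a ratio of 137 (105 to 181), and its 4 tested members each ranged by 4-fold or more. CD74 (ENSG00000019582, chromosome 5, 150401637 to 150412929), the class II invariant chain, ran from 7.56 to 1593 CPM, a ratio of 211 (133 to 356). HLA-DRA rested on 3 counts in its lowest sample and reached 208 CPM in HTO3/HTO9, a ratio of 226 (77.0 to 1100). The MHC class I list started from a higher level and ran from 3061 CPM in HTO2/HTO9 to 16180 CPM in HTO3/HTO9, a ratio of 5.29 (5.17 to 5.40), with 11 of 13 tested members at 4-fold or more. B2M, the light chain of class I molecules, ran from 1545 to 6730 CPM, and the peptide transporter gene TAP1 from 12.6 to 482 CPM. Interferon-stimulated genes of the antiviral type ran from 1134 CPM in HTO4/HTO8 to 6633 CPM in HTO4/HTO9, a ratio of 5.85 (5.62 to 6.09), with 19 of 23 tested members at 4-fold or more. ISG15 ran from 209 to 1542 CPM and IFIT3 from 11.8 to 490 CPM. The low value of IFIT3 rested on HTO7/HTO10, without which its lowest level was 43.3 CPM. Reads of near-identical genes, such as those of HLA class I and class II, SAA1 and SAA2, or CXCL1 to CXCL3, could be divided between copies in counting, so levels of single members are uncertain.

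Genes driven by NF-κB, a transcription factor activated by TNF, ran from 554 CPM in HTO7/HTO10 to 7291 CPM in HTO3/HTO9, a ratio of 13.2 (12.5 to 13.9), and 17 of 22 tested members ranged by 4-fold or more. NFKBIA (ENSG00000100906, chromosome 14, 35401511 to 35404749), which encodes the inhibitor of NF-κB, was lowest in HTO7/HTO10 (34.7 CPM) and highest in HTO2/HTO10 (1435 CPM), a ratio of 41.3 (33.9 to 50.9), or 27.1 without HTO2/HTO10. SOD2, a mitochondrial superoxide dismutase gene, ran from 40.6 to 1835 CPM and the adhesion gene ICAM1 from 32.5 to 1251 CPM. Inflammatory cytokines ran from 64.7 CPM in HTO4/HTO8 to 3962 CPM in HTO3/HTO9, a ratio of 61.3 (52.2 to 72.3), with 13 of 14 tested members at 4-fold or more. CXCL8, which encodes a neutrophil chemokine, ran from 7.14 CPM in HTO4/HTO8 to 817 CPM in HTO3/HTO10, a ratio of 114 (71.3 to 197). CSF3, the granulocyte colony-stimulating factor gene, had 0 counts in HTO1/HTO9 and 242 CPM in HTO3/HTO9, at least 196-fold higher, with 94.1 CPM as its highest level without HTO3/HTO9. CCL5 rested on 1 count in its lowest sample, and its ratio of 897 had an interval of 161 to 35490. Complement and acute-phase genes ran from 135 CPM in HTO2/HTO9 to 2899 CPM in HTO5/HTO8, a ratio of 21.4 (19.5 to 23.6), led by SAA1, a serum amyloid gene, at 51.4 to 1481 CPM.

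**Figure D1:**
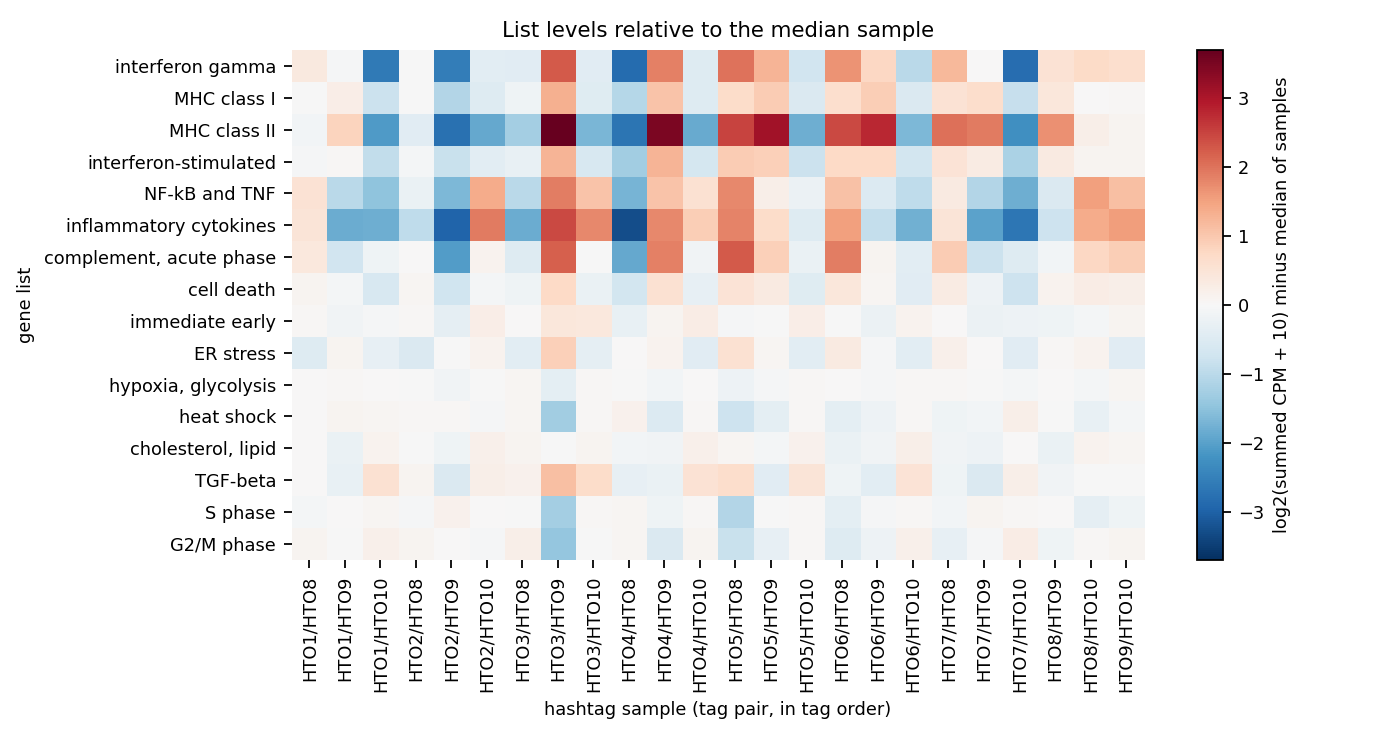
Level of each of 16 gene lists (vertical axis) in each of 24 hashtag samples (horizontal axis), as log2(summed CPM + 10) minus the median of the samples. The MHC class II, inflammatory cytokine and interferon gamma lists show the widest spread, and the hypoxia and cholesterol lists the narrowest.

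Proliferation and heat shock genes were lowest in HTO3/HTO9, the sample with the highest interferon gamma level, the lowest median depth and the highest mitochondrial share. The G2/M phase list ran from 3245 CPM there to 10617 CPM in HTO7/HTO10, a ratio of 3.27 (3.19 to 3.35), with 49 of 54 members at 2-fold or more. Without HTO3/HTO9 the lowest level was 4930 CPM, the ratio 2.15 and the members at 2-fold or more 35. ANLN, which encodes the cytokinesis protein anillin, ran from 33.4 to 278 CPM, and TOP2A, a topoisomerase gene of dividing cells, from 122 to 540 CPM, with lowest levels of 78.0 and 240 CPM without HTO3/HTO9. The S phase list ran from 1247 CPM in HTO3/HTO9 to 3300 CPM in HTO2/HTO9, with 32 of 34 tested members at 2-fold or more, or 26 of 35 without HTO3/HTO9. RRM2, a ribonucleotide reductase gene, ran from 42.6 to 228 CPM, and from 72.1 CPM without HTO3/HTO9. The heat shock list ran from 3987 CPM in HTO3/HTO9 to 11337 CPM in HTO7/HTO10, a ratio of 2.84 (2.78 to 2.91), led by the chaperone gene HSP90AA1 at 2311 to 7142 CPM.

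The TGF-β list had a ratio of 3.22 (3.004 to 3.45). Cell death genes had a ratio of 2.86 (2.69 to 3.05), and TNFSF10, which encodes the death ligand TRAIL, ran from 1.68 to 266 CPM, and from 3.47 CPM without HTO4/HTO8. ER stress genes had a ratio of 2.66 (2.502 to 2.84), with the stress-induced gene DDIT4 at 4.10 to 244 CPM, its highest level being 134 CPM without HTO3/HTO9 and its lowest 6.57 CPM without HTO5/HTO10. Immediate early genes had a ratio of 1.68 (1.60 to 1.77), with JUNB at 5.46 to 84.4 CPM, and from 8.27 CPM without HTO4/HTO8. The genes named from these lists ranged more widely than most members. Of tested members, 3 of 11 cell death, 2 of 8 ER stress and 2 of 8 immediate early genes ranged by 4-fold or more. The hypoxia and glycolysis list had a ratio of 1.36 (1.32 to 1.41) and the cholesterol list one of 1.41 (1.29 to 1.54), and 0 of 7 tested members in each ranged by 4-fold.

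**Figure D2:**
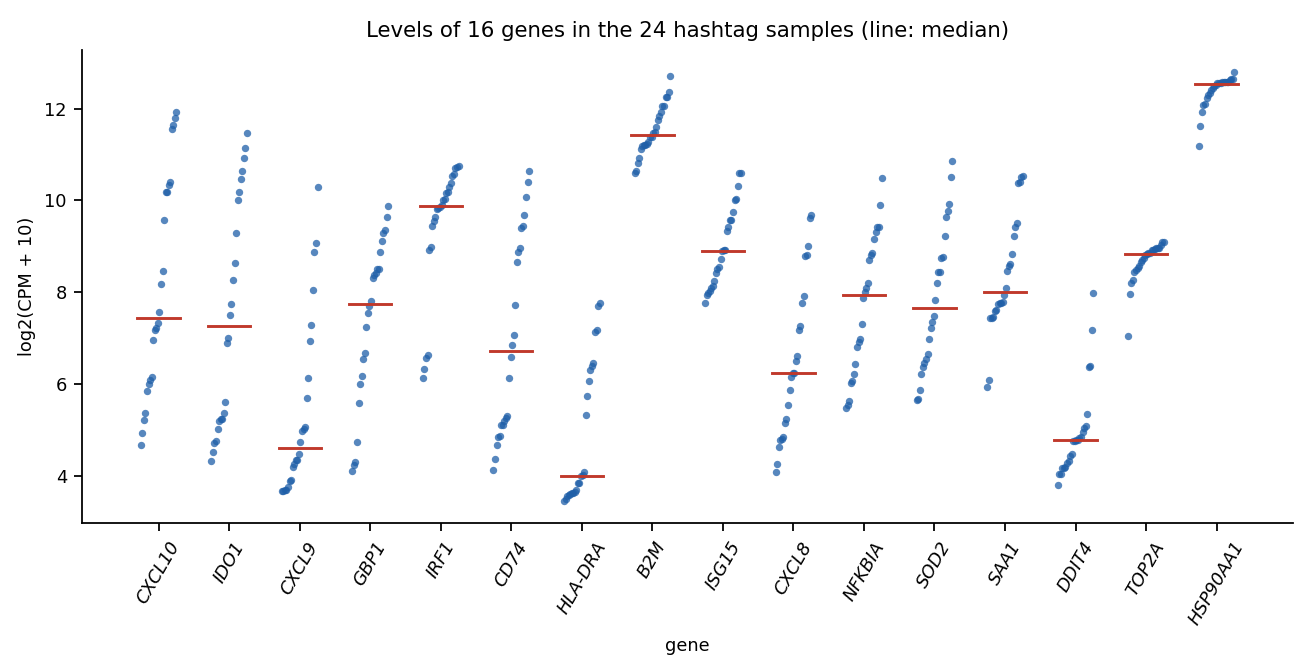
Levels of 16 genes in the 24 hashtag samples, as log2(CPM + 10), with 1 point per sample sorted within each gene and a red line at the median. CXCL10 spans 15.5 to 3896 CPM, while HSP90AA1 spans 2311 to 7142 CPM.

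Over all genes, 238 of 5767 with a mean of 20 CPM or more (4.13%) ranged by 4-fold or more and 1504 (26.1%) by 2-fold or more. Counting error alone gave at most 0 and 1 such genes in 20 simulations. Variation between cultures was not part of these simulations and could not be measured, as each condition had 1 culture. Of the 238 genes, 113 belonged to the lists, 110 were highest in HTO3/HTO9, and 53 were lowest in HTO7/HTO10. Among the 25 genes with the widest range, 9 were interferon gamma genes, 7 inflammatory cytokines, 4 NF-κB genes and 2 acute-phase genes. The count depended on settings, at 402 with a pseudocount of 1 CPM, 82 with 50 CPM and 94 among genes of 100 CPM or more, and it was 168 without HTO3/HTO9.

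Lists were correlated over the 18 samples that remained after 6 were set apart. MHC class I and class II levels moved together (r = 0.990, rho = 0.965), as did the NF-κB and cytokine lists (r = 0.978, rho = 0.934). For both relations the permutation p was 1e-05, the smallest that the resamples can give, the Benjamini-Hochberg adjusted p of r was 9.23e-05, and r without the 2 farthest samples was 0.986 and 0.970. Over these 18 samples the MHC class II and NF-κB lists were not correlated detectably, with r = -0.0259 (95% interval -0.487 to 0.446, permutation p = 0.916, adjusted p = 0.924). Their rho was -0.117 (permutation p = 0.641), and without the 2 farthest samples r was -0.160. The sign of this r changed under another scaling (0.00111) and with 20 samples (0.193). HTO2/HTO10, for example, had a high NF-κB level with a low MHC class II level, and HTO7/HTO9 the opposite. The r of -0.0259 leaves out the 6 samples set apart, although neither list had a wide gap (0.136 and 0.137 of the range). Of the 6, HTO4/HTO8, HTO7/HTO10, HTO1/HTO10 and HTO2/HTO9 were the lowest in both lists. HTO3/HTO9 was the highest in both, and HTO5/HTO8 was above the median in both. An r over all samples is not given here, so independence of the lists over all samples cannot be concluded.

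**Figure D3:**
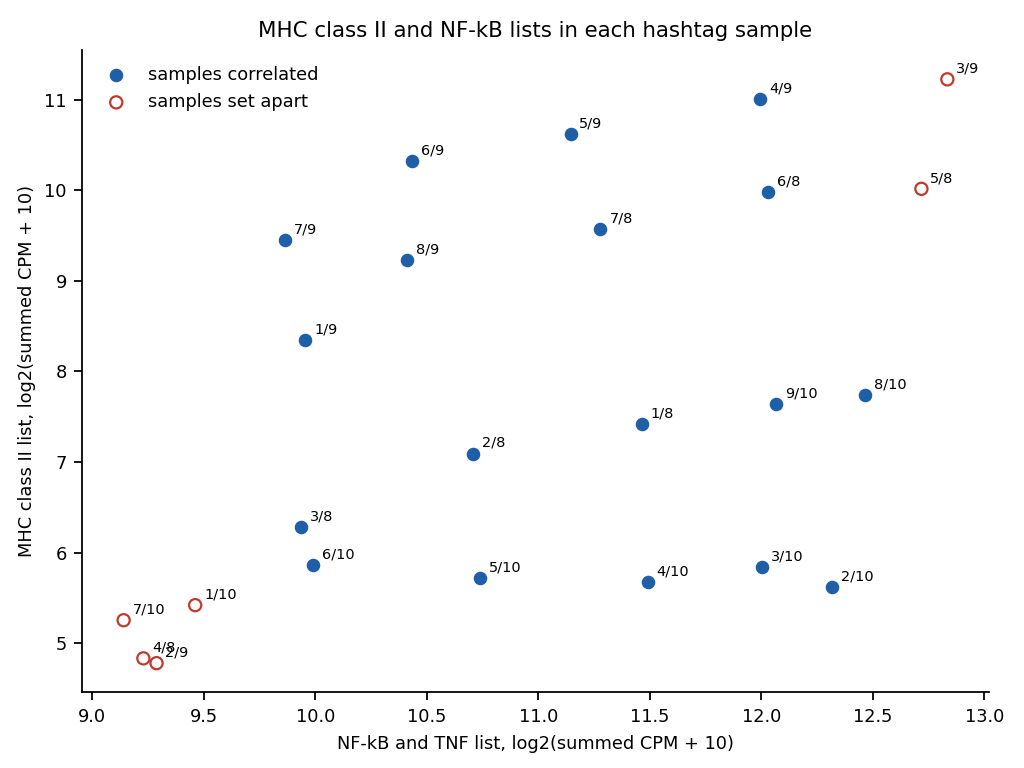
MHC class II list against NF-κB list in 24 hashtag samples, each axis as log2(summed CPM + 10), with points labelled by tag numbers. Filled points are the 18 samples correlated (r = -0.0259) and open points the 6 set apart.

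The interferon gamma list moved with MHC class II (r = 0.879, rho = 0.882), with antiviral genes (r = 0.931, rho = 0.9505) and with cell death genes (r = 0.954, rho = 0.9505), and r without the 2 farthest samples was 0.846, 0.906 and 0.933. It moved against the heat shock list (r = -0.875, rho = -0.880, without the 2 farthest -0.789). In these 4 relations the permutation p of r and of rho was 1e-05, the smallest possible, and the Benjamini-Hochberg adjusted p of r was 9.23e-05. It also moved against the G2/M list (r = -0.846, permutation p = 2e-05, adjusted p = 0.000141; rho = -0.767, permutation p = 0.00032; r without the 2 farthest -0.722). Its relation to the NF-κB list did not pass (r = 0.396, 95% interval -0.0864 to 0.728, permutation p = 0.104, adjusted p = 0.138; rho = 0.321, permutation p = 0.194; 0.234 without the 2 farthest), but passed when only the 4 samples apart in the interferon gamma list were left out (r = 0.576, adjusted p = 0.01445). Complement genes followed both the interferon gamma list (r = 0.847, permutation p = 1e-05, adjusted p = 9.23e-05; rho = 0.789, permutation p = 0.00016; 0.725 without the 2 farthest) and the NF-κB list (r = 0.710, permutation p = 0.00097, adjusted p = 0.00291; rho = 0.736, permutation p = 0.00081; 0.635 without the 2 farthest). TGF-β genes moved against MHC class I (r = -0.903, rho = -0.922, permutation p = 1e-05 for each, adjusted p = 9.23e-05; -0.919 without the 2 farthest), but this relation did not pass with 20 samples (r = -0.307, adjusted p = 0.233), which add HTO3/HTO9 and HTO5/HTO8, both above the median in each list. Of 120 pairs, 67 passed by r, 31 of them positive and 36 negative, and 61 passed by both r and rho. These counts take the samples as independent, although the conditions shared doses and times. The median mitochondrial share of a sample also rose with the interferon gamma list (r = 0.733, permutation p = 0.00082, adjusted p = 0.00187; rho = 0.647, permutation p = 0.00445; 0.561 without the 2 farthest). It fell with the heat shock list (r = -0.762, permutation p = 0.00023, adjusted p = 0.00092; rho = -0.661, permutation p = 0.00355; -0.591 without the 2 farthest) and with the G2/M list (r = -0.8997, permutation p = 1e-05, the smallest possible, adjusted p = 0.00016; rho = -0.827, permutation p = 5e-05; -0.838 without the 2 farthest). The mitochondrial share passed by r as well with MHC class I (0.733), MHC class II (0.787), antiviral (0.748), ER stress (0.817), cell death (0.593) and complement genes (0.561). Negative values passed by r for TGF-β (-0.536), hypoxia (-0.516) and cholesterol genes (-0.619). By rho, complement (0.356, adjusted permutation p = 0.180) and hypoxia genes (-0.457, adjusted permutation p = 0.0779) did not pass, while the other lists that passed by r did. Without the 2 farthest samples r was 0.206 for complement, 0.367 for cell death and -0.400 for hypoxia genes. The NF-κB (0.116), cytokine (0.184), immediate early (-0.381) and S phase lists (-0.345) did not pass. With cells of at least 2000 genes and at most 10% mitochondrial UMIs, the interferon gamma list had r = -0.830 with the heat shock list and -0.785 with the G2/M list. No label tied a cell to 1 of the 2 gene-expression libraries, and no other batch was recorded within the pool. Values within batches could therefore not be given.

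Single cells varied most in KRT81, a hair keratin gene, whose variance was 84.7 times that of Poisson sampling, and in MALAT1, a nuclear noncoding RNA (60.1 times). CXCL10 followed among the list genes (37.1 times), with 57.8% of its excess lying between hashtag samples, against 0.956% for KRT81. In all, 840 of 10125 genes had a ratio of 1.5 or more, 156 of them in the lists, and 142 did after thinning to 1 depth. CXCL10 had a UMI in 61.7% of kept cells (60.5% to 62.9%), and in 43.0% after thinning. Thinned shares ran from 4.27% of 164 cells in HTO4/HTO8 to 97.9% of 233 cells in HTO5/HTO8. No cell type known to lack CXCL10 was present, but all samples shared 1 pool and its free RNA, so the 7 of 164 cells in HTO4/HTO8 (interval 1.73% to 8.596%) limit the share that free RNA gave. Over 6314 thinned cells the interferon gamma and NF-κB scores had r = 0.596 and rho = 0.608, without a p-value since cells are not replicates, and the median r within hashtag samples was 0.315.

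Clustering gave 11 clusters of cells, described here by number. Cluster 2 (833 cells) was led by class II genes such as HLA-DPB1 and HLA-DRB1, cluster 6 (712 cells) by CCL20, TNF and TNFAIP3, and cluster 5 (736 cells) by FABP4. Cluster 7 (668 cells), 35.2% of whose assigned cells came from HTO3/HTO9, had the highest interferon gamma level, 13957 CPM, and the lowest G2/M level, 2895 CPM. Its MHC class II level (1716 CPM) exceeded that of cluster 2 (1260 CPM), and its NF-κB and cytokine levels (5438 and 2553 CPM) those of cluster 6 (4101 and 2236 CPM). Cluster 8 (248 cells, 3.87%, interval 3.41% to 4.37%) expressed KRT81 at 3040 CPM against 5.84 CPM in the other cells, 7.56% of which nevertheless had a KRT81 UMI. Median depths were 18401 and 13406.5 UMIs, and the source of these UMIs was not tested. Cluster 8 held MTAP at 45.2 CPM, CDKN2A at 68.1 CPM and CDH1 at 48.8 CPM, against 0.124, 0.124 and 0.158 CPM in the other cells. Its 10 leading genes by fold included 1 T cell marker, TRBC2 (64.7 against 0.0563 CPM), and 0 epithelial markers, while CD3E and PTPRC, other T cell markers, had 0 UMIs in it. Epithelial markers were nevertheless expressed in cluster 8, with EPCAM at 269 against 36.2 CPM, KRT7 at 964 against 535 and KRT18 at 1827 against 1593 CPM. KRT8 was somewhat lower, at 561 against 700 CPM. The mesenchymal gene VIM was lower there, 536 against 2304 CPM. In the 5298 cells with a hashtag sample, all 8 epithelial markers had at least 50 UMIs. Of 14 T cell markers 7 had 0 UMIs and 3 had at least 50, as had 1 of 5 B cell, 3 of 8 myeloid, 0 of 7 fibroblast and 1 of 6 endothelial markers. Part of these counts came from cluster 8. Over all kept cells, CDH1 had 230 UMIs in cluster 8 and 14 in the other cells, and TRBC2 had 305 and 5. The myeloid marker S100A9 had 4332 UMIs in cluster 8 (919 CPM) and 261 in the other cells (2.94 CPM).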

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

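Both tests of doublets and both tests of Katushka were chosen only after the result was seen, while those of tag counts and of shared wells were set beforehand.

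In cluster 8, 104 of 248 cells had no hashtag sample, so that they lie outside the comparisons of samples. These cells carried a transcriptome unlike that of the other cells, with MTAP, CDKN2A and CDKN2B, which lie side by side on chromosome 9 (21802543 to 22009363), at 45.2, 68.1 and 5.94 CPM against 0.124, 0.124 and 0.0113 CPM. Doublets were tested by 2 counts: the first came out as doublets would give it, as 0 of 1029 genes abundant in every other cluster lay below 0.25 of their lowest level in the other clusters, and the second, added after that outcome, argues against doublets of the other clusters, as 126 of 6034 genes exceeded 4 times the highest other cluster. Cells added after hashing are argued against by tag counts of 0.872 times those of other cells (0.743 to 1.007). In the cluster's cells with a hashtag sample, the interferon gamma list followed that of the other cells of the same tag pair (rho = 0.877, 95% interval 0.624 to 0.993). The permutation p of rho was 1e-05, the smallest possible, and r was 0.927, or 0.892 without the 2 farthest. This relation rested on 17 samples with between 3 and 11 cells of the cluster each. The 104 cells without a sample did not enter it. A second cell population that shared the wells is therefore a candidate explanation, as a hypothesis, and doublets between it and the other cells stay open for part of the cluster, given its median of 18401 UMIs and its 41.9% of cells without a sample.

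Katushka, a far-red fluorescent protein added to the reference as a gene of its own, had 420 UMIs over all barcodes, above the 3 counts that a count of 0 allows. Its level ran from 0 counts in HTO4/HTO8 and HTO7/HTO10 to 11.3 CPM in HTO7/HTO8, with a median of 4.08 CPM. Over 18 samples it followed the interferon gamma list (rho = 0.775, 95% interval 0.404 to 0.944, permutation p = 0.00034, adjusted p = 0.00283; r = 0.814, and 0.720 without the 2 farthest), 10 of 16 lists passed by rho, among them MHC class I (0.721), cell death (0.740) and, negatively, S phase (-0.707) and cholesterol genes (-0.600), and rho with MHC class II exceeded rho with NF-κB by 0.755 (0.173 to 1.27). A reporter that responds to interferon may account for this, as a hypothesis that the other relations do not single out, and no source used here says how the gene was carried. Free RNA of the shared pool is limited by the samples with 0 counts (3 counts would be 1.04 CPM in HTO7/HTO10), while misassigned reads were not tested and stay open.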

How the results depend on the processing

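Leaving out clusters 8, 10 and 11, using 20 samples in place of 18, leaving out cells without a sample, leaving out HTO3/HTO9, stricter cells for list correlations, and values within samples were chosen after seeing the data. The 238 genes with a range of 4-fold became 402 with a pseudocount of 1 CPM, 82 with 50 CPM and 94 at a mean of 100 CPM or more, by construction of the measure and of the filter, and 15, 20 and 19 of the 25 widest-ranging genes were shared; leaving out HTO3/HTO9 gave 168 genes and the other alternatives 216 to 311. Kept cells numbered 10660 with no filter and 2697 with 2000 genes and 10% mitochondrial UMIs, by construction. Genes with excess variance numbered 142 after thinning, 1750 at a lower ratio and 433 at a ratio of 2, by construction for the ratios. A fall on thinning is also by construction, as the excess over Poisson sampling shrinks with a cell's depth. Whether the lower depth accounts for the whole change was not tested.

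With 20 samples, the interferon gamma and NF-κB lists passed (r = 0.576), TGF-β genes and MHC class I no longer passed (-0.307 against -0.903), the added samples HTO3/HTO9 and HTO5/HTO8 lying above the median in each, and r of the NF-κB list turned positive with MHC class I (0.182) and class II (0.193); with TMM scaling the last was 0.00111. None of these 3 turned values had passed, and the cause was not tested. The relations described were picked from 120 pairs. Over all 120, TMM scaling left 100 the same, 11 weaker, 4 stronger and 5 with another sign, none of which had passed. With 20 samples 68 were the same, 12 weaker, 27 stronger and 13 had another sign, 3 of which had passed: TGF-β genes with ER stress, heat shock and G2/M genes. Removing clusters 8, 10 and 11 left 117 the same, pseudocounts of 1 and 50 CPM 119 each, and stricter cells 102, with 12 weaker, 1 stronger and 5 of another sign, none of which had passed.

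The r of 0.596 between interferon gamma and NF-κB scores over cells was 0.712 without thinning, 0.510 and 0.630 with pseudocounts of 10 and 1000 CPM, 0.565 with stricter cells, 0.476 without the highest member of each list and 0.315 as the median within samples; the cause was not tested. Cells with CXCL10 were 43.0% after thinning, 52.3% with all barcodes and 56.8% with stricter cells, and the cause was not tested beyond the lower depth that thinning sets. Clusters numbered 7 at resolution 0.25 and 18 at 1.0, as the resolution sets their number. Of other values, 134 of 176 list ranges, 903 of 1089 gene ranges and 50 of 120 shares stayed within counting error. The shares include those after removal of the 2 called doublets, which could hardly move a share, so the 50 overstate how many stayed. Removing doublets was void, as the caller had failed; leaving out genes shared between lists moved nothing, as there were none. Analysis by barcode suffix and the tests of known conditions were not run. No paired analysis was possible because no sample could be tied to a condition.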

Other observations

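The test of the S phase samples was set before its result, though after the unthinned levels, was seen, and genes and clusters below were picked after their values were seen.

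A group of 223 cells, cluster 9, carried an antiviral program, and a small part of them had reads of an interferon gene. OASL and RSAD2, antiviral effectors, stood at 538 and 193 CPM against 13.97 and 3.19 CPM in the other cells, and IFIT1 and IFIT2 at 255 and 457 CPM against 11.7 and 15.3 CPM. The chemokine gene CCL5 stood at 474 against 19.6 CPM. IFNL1, which encodes an interferon lambda, had 47 UMIs in this cluster and 5 in all other cells, 14.1 against 0.0554 CPM. Only 8.52% of the cluster's cells had an IFNL1 UMI, against 99.1% for OASL. These genes define the cluster, so their levels are a description and not a test. The cells occurred in all 24 hashtag samples, from 0.493% of cells in HTO7/HTO10 to 16.7% in HTO4/HTO9 (12.1% to 22.2%).

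Of the 238 genes with a range of 4-fold or more, 125 were in no list. C15orf48 ran from 1.64 CPM in HTO1/HTO9 to 547 CPM in HTO3/HTO9 (170 CPM at most without HTO3/HTO9 and 2.52 CPM at least without HTO1/HTO9), and IL18BP, which encodes an inhibitor of interleukin 18, from 2.08 CPM in HTO7/HTO10 to 207 CPM in HTO3/HTO9. UBE2L6, the ubiquitin-like conjugating enzyme gene for ISG15, ran from 17.2 CPM in HTO1/HTO10 to 432 CPM in HTO4/HTO9. Other genes ran the opposite way between such samples. FABP4, a fatty acid binding protein gene, was highest in HTO4/HTO8 (118 CPM) and lowest in HTO4/HTO9 (1.33 CPM), without which its lowest level was 2.13 CPM. THBS1, which encodes thrombospondin, was highest in HTO7/HTO10 (168 CPM) and lowest in HTO3/HTO9 (9.55 CPM). The keratin gene KRT7 ran from 136 CPM in HTO4/HTO9 to 937 CPM in HTO3/HTO10, and AREG, a growth factor gene, from 84.8 CPM in HTO5/HTO8 to 526 CPM in HTO2/HTO9, and from 162 CPM without HTO5/HTO8.

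The interferon gamma list fell into separate clusters of samples. HTO4/HTO8 had 528 CPM, HTO7/HTO10 534, HTO1/HTO10 614 and HTO2/HTO9 650 CPM. After a gap of 0.303 of the range came HTO6/HTO10 with 1918 CPM, HTO5/HTO10 with 2354, HTO4/HTO10 with 2787, HTO3/HTO8 with 2853, HTO3/HTO10 with 2862, HTO2/HTO10 with 2915, HTO1/HTO9 with 3769, HTO2/HTO8 with 3801, HTO7/HTO9 with 3896 and HTO1/HTO8 with 4960 CPM. HTO8/HTO9 had 5537 CPM, HTO9/HTO10 5928, HTO8/HTO10 6323, HTO6/HTO9 6503, HTO7/HTO8 8846, HTO5/HTO9 9250, HTO6/HTO8 12164, HTO4/HTO9 14042, HTO5/HTO8 15561 and HTO3/HTO9 18568 CPM. No condition can be read from these values.

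In the complement list, HTO2/HTO9 (135 CPM) and HTO4/HTO8 (151 CPM) stood below the other samples by 0.254 of the range, of which HTO7/HTO9 had the lowest value at 335 CPM.

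In the S phase list, HTO3/HTO9 (1247 CPM) and HTO5/HTO8 (1398 CPM) stood below the other 22 samples by 0.527 of the range. The other values were 2336 CPM in HTO6/HTO8, 2350 in HTO8/HTO10, 2668 in HTO9/HTO10, 2680 in HTO4/HTO9, 2772 in HTO7/HTO8, 2818 in HTO1/HTO8, 2893 in HTO2/HTO8, 2905 in HTO6/HTO9, 2941 in HTO3/HTO8, 2955 in HTO5/HTO9, 3015 in HTO1/HTO9 and 3016 in HTO8/HTO9. They were 3034 CPM in HTO2/HTO10, 3059 in HTO4/HTO10, 3064 in HTO7/HTO10, 3085 in HTO6/HTO10, 3092 in HTO5/HTO10, 3097 in HTO3/HTO10, 3144 in HTO1/HTO10, 3169 in HTO4/HTO8, 3183 in HTO7/HTO9 and 3300.3 in HTO2/HTO9. With cells of at least 2000 genes and at most 10% mitochondrial UMIs, thinned to 1 depth, the same samples stayed below by 0.370 of the range, above the limit of 0.243, which argues against lower cell quality as the whole cause. The fewest cells of a sample in this test were 30, and no biological explanation was tested.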
